A study of Homo sapiens with 18 samples.

How the data were processed

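The study measured newly made messenger RNA in human neuroblastoma cells after loss of SMARCA4 activity. There were 18 libraries in 9 groups of 2. IMR-32, KELLY and SK-N-DZ cells received either 1 uM BRM014, an inhibitor of the ATPases SMARCA4 and SMARCA2, or DMSO. IMR-32 cells carrying SMARCA4 fused to a mini auxin-inducible degron (SMARCA4-mAID) received either 500 uM auxin or ethanol. Cells were given 500 uM of the nucleoside analogue 4-thiouridine (4sU) for 2 h before harvest, except for 2 KELLY libraries that were left unlabelled. Per the labels' protocols, RNA from labelled cells was treated with iodoacetate, messenger RNA was captured on poly(dT), and fragments were size-selected before amplification. How long the cells were exposed to BRM014 or auxin is not given in the sources used here. Groups and replicate numbers were taken from the sample labels.

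Each deposited file holds raw counts per gene symbol, which the authors made before deposit and which their name describes as conversion counts. HISAT, HTSeq, DESeq2 and the build hg38 are listed in the submitters' processing notes, without versions or roles. The rule by which a read entered the count, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense gene pairs, such as DBH and DBH-AS1, MYCN and MYCNOS, GATA3 and GATA3-AS1, or DNM3OS and DNM3, and reads of near-identical copies, such as ribosomal protein pseudogenes, could therefore have been assigned to either gene, and values of such genes are uncertain. A file lists 28063 genes and ends with the summary lines that HTSeq writes. These lines were kept out of library sizes and tests. Reads listed there as having no feature made up 46.4% to 57.4% of the assigned and unassigned total in labelled libraries and 65.2% to 66.7% in unlabelled ones. As the annotation and strand setting are not given, these reads need not lie outside genes. Ambiguous reads made up 1.11% to 1.71% in labelled libraries.

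Counts assigned to genes ranged from 724913 to 1740475 per labelled library, with 13327 to 15279 genes detected. The unlabelled libraries held 5395 and 4432 counts. The spread between the 2 libraries of a group corresponded to a biological coefficient of variation of 0.143, and chi-square statistics per degree of freedom of 2.37 to 4.37 gave no sign that a library had been deposited more than once. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Counting intervals and floors cover counting error only.

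Differential abundance was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) scaling factors and the filterByExpr filter, which kept 12853 genes. All 16 labelled libraries entered a group-means model with 8 residual degrees of freedom. The contrasts were BRM014 against DMSO in each line, the mean of these effects over the 3 lines, the difference of the effect among lines, auxin against ethanol, and the BRM014 effect in IMR-32 minus the auxin effect. Labelled and unlabelled KELLY libraries were compared in a separate model of 4 libraries over 8443 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are treated over control, with standard errors (SE) from the fit. They are relative to the other genes of a library, so a change in new RNA common to all genes would not show. A fold against a group without counts was taken against a floor of 3 counts over the group, and ratios resting on 1 to 3 counts have exact binomial 95% intervals. No pair of contrasts whose overlap is given shares control libraries.

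The tests, the named genes, the gene lists and the alternatives listed last were fixed before the data were examined, except those marked as added. Named genes were the 10 highest and 10 lowest called genes of a comparison with both treated libraries beyond both control libraries and a mean count of at least 50 in the higher group, the 6 smallest p of each test of differences, 10 fixed genes (among them SMARCA4, SMARCA2, MYCN, PHOX2A, HAND2, GATA3, ISL1 and TBX2), and up to 4 members of each list with the smallest p. For the mean over lines the ranking took genes called the same way in all 3 lines. Unnamed transcripts and small RNAs were left out of the rankings, and some named genes are not reported here. The 20 lists cover adrenergic regulators, noradrenergic function, mesenchymal regulators, Schwann lineage markers, SWI/SNF (BAF) subunits, immediate early genes, nucleolar MYC targets, ribosomal proteins, mitochondrially encoded genes, DNA replication and E2F targets, G2/M mitosis, p53 targets, cholesterol synthesis, the ATF4 and unfolded protein stress response, heat shock, aryl hydrocarbon receptor targets, HOX genes, axon guidance, neurotrophin and receptor tyrosine kinase signalling, and neuronal channels and vesicles. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. No mitochondrially encoded gene is among the genes in the files used here, so 19 lists were tested. Gene coordinates are from GENCODE release 29 on GRCh38 (hg38).

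On simulated counts with known changes, the edgeR fit recovered 92.4% of genes changed 4-fold, 50.7% changed 2-fold and 17.9% changed 1.5-fold in the IMR-32 comparison. In the 4 treatment comparisons the changed genes came from those above a minimum mean count, not from all genes tested. The corresponding shares were 95.5%, 59.7% and 22.4% in KELLY and 86.4%, 47.8% and 19.4% in SK-N-DZ. In the auxin arm they were 89.4%, 61.2% and 20.9%. Without a trend with base composition, 2 to 6 of 105 to 122 calls were false. With a GC trend of set size added to the treated libraries and left uncorrected, 906 of 1024 calls were false in IMR-32. False calls were then 1444 of 1574 in KELLY, 1203 of 1337 in SK-N-DZ and 1304 of 1436 in the auxin arm. With the transcript property correction listed below, they were 1 of 103, 7 of 115, 4 of 105 and 10 of 125. That trend was not fitted to the data, and the main fit leaves such trends uncorrected. In the labelled-unlabelled comparison the changed genes were drawn from all its genes. There 22.9% of 4-fold changes were recovered and 10 of 23 calls were false, so that its calls were unreliable.

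Alternatives were median-of-ratios scaling, total counts as the only scaling, DESeq2 1.42.0, no filter, a filter of 50 counts, a minimum absolute log2 fold change of 1, a replicate block, leaving out each library, fitting the compared groups alone, leaving out genes whose unlabelled count exceeded 20% of the labelled one, fry in place of camera, and correlations over genes above the median level. Added after the data were seen were thinning of every library to the smallest total, an offset correction of each library for T content, GC content and length of the longest annotated transcript (natural splines of 4 degrees of freedom, properties computed with seqkit 2.13.0), and robust empirical Bayes. Figures were drawn with matplotlib 3.10.9.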

Results

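The series asked how transcription in neuroblastoma cells responds when the chromatin remodelling ATPase SMARCA4 (also called BRG1) is inhibited or degraded. Newly made RNA was counted in IMR-32, KELLY and SK-N-DZ, established neuroblastoma lines with amplified MYCN, with 2 libraries per group. Control libraries held 1438139 and 1148208 gene counts in IMR-32, 1590402 and 1235931 in KELLY, 1589230 and 1740475 in SK-N-DZ, and 1505905 and 1638317 in ethanol-treated SMARCA4-mAID cells. With BRM014 the totals were 741970 and 775064 in IMR-32, 1505376 and 1512030 in KELLY, and 724913 and 758288 in SK-N-DZ. Auxin-treated cells gave 1376718 and 1612020 counts. The unlabelled KELLY libraries, which measure background, gave 5395 and 4432, or 0.348% of the labelled KELLY DMSO total. This and the other background percentages are ratios of raw counts, not scaled for sequencing depth.

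SMARCA4 (chromosome 19, 10960825 to 11079426, plus strand) was not called in any of the 4 treatment comparisons. Levels are in counts per 1e6 (CPM) of a library's total over tested genes, multiplied by its TMM factor. SMARCA4 was at 98.8 ± 11.8 (SD, n = 2) in IMR-32 with DMSO and 82.0 ± 1.31 with BRM014, 109 ± 2.17 and 115 ± 15.7 in KELLY. It was 154 ± 13.6 and 118 ± 15.0 in SK-N-DZ. The individual counts were 123 and 117 in IMR-32 DMSO, 55 and 59 in IMR-32 BRM014, 184 and 141 in KELLY DMSO, and 159 and 197 in KELLY BRM014. SK-N-DZ had 274 and 263 with DMSO and 81 and 102 with BRM014. In the SMARCA4-mAID line the gene reached 809 ± 81.8 CPM with ethanol (1091 and 1379 counts) and 635 ± 39.99 with auxin (887 and 942 counts). The auxin change of -0.35 on the log2 scale was not called (adjusted p = 0.109), and auxin degrades the protein, which RNA counts do not measure. SMARCA2, the paralogous ATPase on chromosome 9 (1980290 to 2193624), had 0 counts in the KELLY libraries and 0 to 5 per library in SK-N-DZ, and was at -0.65 in IMR-32 (adjusted p = 0.700), so that no change was detectable at this depth.

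**Figure D1:**
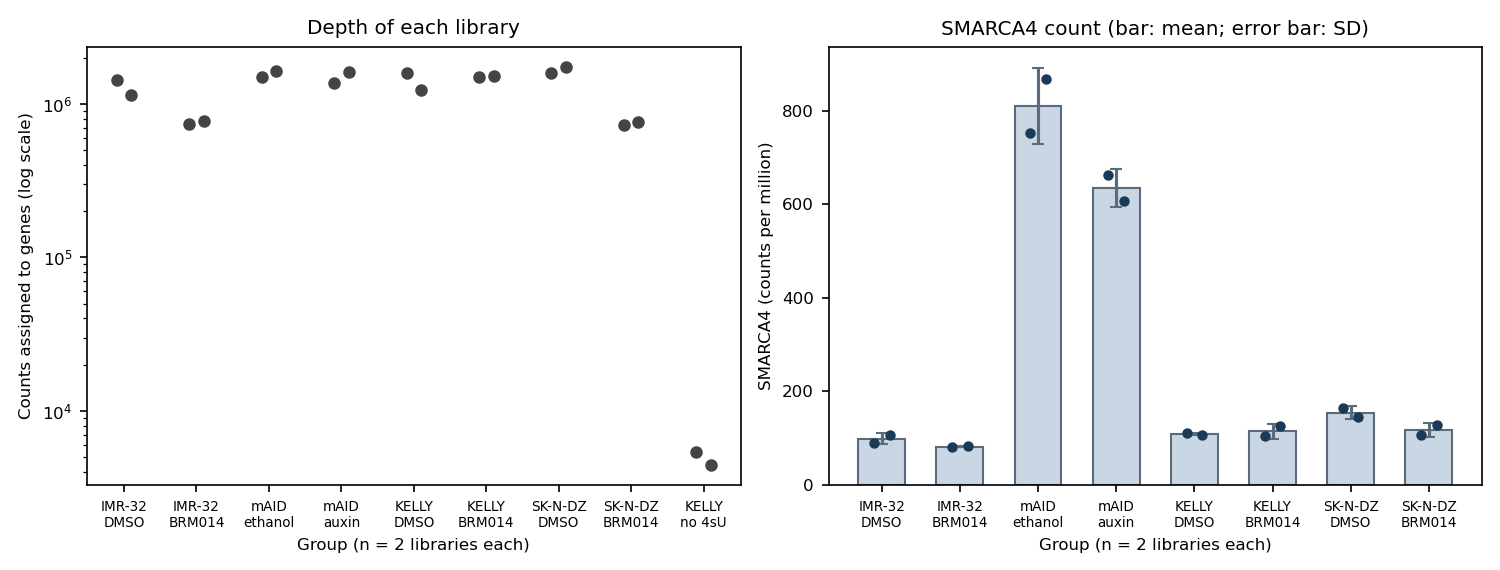
Left, counts assigned to genes in each of the 18 libraries on a log scale, with the 2 unlabelled KELLY libraries at 5395 and 4432. Right, SMARCA4 in CPM for the 16 labelled libraries (points), with group means (bars) and SD (error bars, n = 2 libraries); the SMARCA4-mAID groups stand at 809 and 635 and the other groups between 82.0 and 154.

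In IMR-32, DNA replication genes fell with BRM014, and single genes such as DKK1 and IGFBP4 moved by larger amounts. DKK1, a secreted inhibitor of Wnt signalling (chromosome 10, 52314296 to 52318042), rose by 2.24 on the log2 scale (SE 0.11, adjusted p = 1.58e-30). ID4, which restrains basic helix-loop-helix factors, rose by 2.74 (SE 0.25), and the neural crest factor SOX9 by 2.15 (SE 0.34). FOXC1 rose by 2.29 (SE 0.20) and NPR3, the natriuretic peptide clearance receptor, by 3.52 (SE 0.57). IGFBP4, an insulin-like growth factor binding protein, fell by 4.44 (SE 0.55). The placental growth factor gene PGF fell by 2.77 (SE 0.33) and NRP1, a semaphorin co-receptor, fell by 2.65 (SE 0.23). The cholecystokinin receptor CCKAR went from 126 counts to 1, a ratio of 71.4 with a 95% counting interval of 12.6 to 2843. That count was in BRM014 replicate 2, without which the fitted log2 value was -9.08.

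Of 30 DNA replication and E2F targets, 20 fell and 0 rose in IMR-32 (22 and 0 adjusted over the list alone), with a median log2 change of -0.89 (list adjusted p = 1.05e-17, and adjusted p = 0.0254 with an estimated correlation). UHRF1, E2F2 and MCM4 fell by 1.71, 1.61 and 1.16. Among heat shock factor targets 7 of 16 fell and 0 rose (9 fell adjusted over the list alone, adjusted p = 8.16e-06, and adjusted p = 0.0640 with an estimated correlation). HSPA8, a constitutive HSP70 chaperone, fell by 1.03 and FKBP4 fell by 1.52. Of 60 ribosomal protein genes 13 fell and 0 rose (15 fell adjusted over the list alone, adjusted p = 5.54e-05, and adjusted p = 0.0996 with an estimated correlation). RPLP0, for example, fell by 0.65. Nucleolar MYC targets had 5 of 30 lower (5 adjusted over the list alone, adjusted p = 0.0218, and adjusted p = 0.275 with an estimated correlation), and LDHA and HSPD1 fell by 0.74 and 0.51. Of 23 p53 targets 5 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0345, and adjusted p = 0.327 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, fell by 1.66 (SE 0.35) and TP53INP1 rose by 1.58 (SE 0.16). Reads listed as having no feature made up 57.3% and 57.4% of the IMR-32 libraries with BRM014 against 50.8% and 53.5% with DMSO. With BRM014, at lower totals, 13327 and 13517 genes were detected against 14516 and 14513. In total 1650 of 12853 genes were called by edgeR, 805 higher and 845 lower. Without DMSO replicate 1 the number was 922, without BRM014 replicate 1 it was 985, and without BRM014 replicate 2 it was 1091.

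In KELLY, catecholamine genes fell and axon guidance genes rose with BRM014. TH (chromosome 11, 2163929 to 2171877), the rate-limiting enzyme of catecholamine synthesis, went from 286 counts to 1, a ratio of 297 with a 95% counting interval of 52.8 to 11752. The receptor tyrosine kinase gene RET (chromosome 10, 43077027 to 43130351) fell by 5.54 on the log2 scale (SE 0.45, adjusted p = 1.42e-18), and GFRA2, a neurturin receptor, fell by 3.68 (SE 0.34). P2RY6, a nucleotide receptor, was at least 35.6-fold lower, with 0 counts against 103. GATA6 rose by 5.15 (SE 0.79) from 5 counts to 194, and the laminin gene LAMA4 by 4.17 (SE 0.81). The Wnt pathway regulator DACT1 rose by 3.86 (SE 0.33), FOXC1 by 3.71 (SE 0.28) and the metalloproteinase inhibitor TIMP3 by 3.55 (SE 0.24). DNM3OS, which lies antisense to DNM3, rose by 4.09 (SE 0.39), with an unlabelled background of 25% of its 6 counts per DMSO library.

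The noradrenergic function list had 12 of 26 members lower and 3 higher in KELLY (12 and 4 adjusted over the list alone, adjusted p = 2.48e-05, and adjusted p = 0.0155 with an estimated correlation). DBH, which makes noradrenaline, fell by 2.90, CYB561 fell by 1.76, and MAOA, which degrades catecholamines, rose by 2.38. Of 46 axon guidance genes 20 rose and 5 fell (21 and 5 adjusted over the list alone, adjusted p = 1.37e-06, and adjusted p = 0.0155 with an estimated correlation). NRP2, CNTN1 and EFNA5 rose by 2.52, 2.33 and 2.26, and PLXNA1 fell by 2.18. The DNA replication list fell, with 16 of 30 members lower and 0 higher (22 lower adjusted over the list alone, adjusted p = 1.86e-10, and adjusted p = 0.0325 with an estimated correlation). RRM2 and MCM4 fell by 0.67 and 0.70. Heat shock genes fell in 8 of 16 cases (12 adjusted over the list alone, adjusted p = 7.72e-06, and adjusted p = 0.0325 with an estimated correlation). Ribosomal proteins fell in 11 of 60 (15 adjusted over the list alone, adjusted p = 7.72e-06, and adjusted p = 0.0332 with an estimated correlation).

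Another 8 lists were called in KELLY but not with an estimated correlation. Cholesterol synthesis genes rose in 7 of 24 cases and fell in 0 (7 and 1 adjusted over the list alone, adjusted p = 0.00190, and adjusted p = 0.0969 with an estimated correlation). STARD4 and CYP51A1 rose by 0.85 and 0.71. BAF subunits rose in 6 of 29 cases and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0163, and adjusted p = 0.0617 with an estimated correlation). BICRAL rose by 1.65 and ARID2 by 0.94. Mesenchymal regulators rose in 4 of 19 cases and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.0487, and adjusted p = 0.0969 with an estimated correlation), with TWIST1 higher by 1.41. Channels and vesicle genes rose in 9 of 38 cases and fell in 3 (9 and 3 adjusted over the list alone, adjusted p = 0.0357, and adjusted p = 0.0636 with an estimated correlation), and SYT1 rose by 1.47. Stress response genes fell in 5 of 26 cases (5 adjusted over the list alone, adjusted p = 4.53e-04, and adjusted p = 0.0617 with an estimated correlation), as did p53 targets in 6 of 23 with 1 higher (6 and 1 adjusted over the list alone, adjusted p = 0.00401, and adjusted p = 0.0969 with an estimated correlation). Nucleolar MYC targets fell in 7 of 30 (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.0143, and adjusted p = 0.101 with an estimated correlation), and G2/M genes in 4 of 30 (4 adjusted over the list alone, adjusted p = 0.0370, and adjusted p = 0.170 with an estimated correlation). HSPA5 and XBP1 fell by 0.89 and 1.00, CDKN1A by 2.80, NCL by 0.46 and MKI67 by 0.57. Altogether 1485 genes were called, 845 higher and 640 lower, against 872 without DMSO replicate 1 and 904 without BRM014 replicate 1.

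In SK-N-DZ, DNA replication genes fell while mitotic genes rose, relative to the other genes of the libraries. Gene counts were lower with BRM014 (724913 and 758288) than with DMSO (1589230 and 1740475), and absolute amounts of new RNA were not measured. Of 30 DNA replication genes 25 fell and 0 rose (27 fell adjusted over the list alone, median log2 change -1.14, adjusted p = 5.66e-23, and adjusted p = 0.00495 with an estimated correlation). UHRF1 fell by 2.31, MCM3 by 1.64 and MCM6 by 1.77. Of 30 G2/M genes 18 rose and 0 fell (22 rose and 1 fell adjusted over the list alone, median 0.53, adjusted p = 1.22e-10, and adjusted p = 0.00495 with an estimated correlation). CDK1 rose by 0.94, the topoisomerase TOP2A by 0.72 and the spindle checkpoint kinase TTK by 1.05. RET went from 416 counts to 2, a ratio of 92.1 with a 95% counting interval of 25.3 to 763. DBH fell by 4.86 (SE 0.40), CDKN1A fell by 4.90 (SE 0.46) and PGF fell by 5.26 (SE 0.41). DKK1 rose by 3.56 (SE 0.19, adjusted p = 8.78e-30) and the nuclear receptor ESRRG by 3.92 (SE 0.27). The protocadherin FAT4 rose by 3.77 (SE 0.37) and PLK2 by 2.83 (SE 0.22). The long non-coding RNA MEG3 fell by 4.48 (SE 0.57), with an unlabelled background of 65% of its 10 counts per library in KELLY. Without BRM014 replicate 2 the values of CDKN1A and MEG3 were -10.52 and -9.88, as the remaining library had 0 counts of each.

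Noradrenergic function genes fell in 11 of 26 cases and rose in 1 in SK-N-DZ (11 and 1 adjusted over the list alone, adjusted p = 2.86e-05, and adjusted p = 0.00495 with an estimated correlation). CYB561 fell by 3.37 and the noradrenaline transporter SLC6A2 fell by 1.35. Ribosomal proteins fell in 28 of 60 cases (33 adjusted over the list alone, adjusted p = 1.97e-11, and adjusted p = 0.00495 with an estimated correlation), and RPL10 fell by 1.15. Nucleolar MYC targets fell in 16 of 30 cases (17 lower and 1 higher adjusted over the list alone, adjusted p = 1.31e-07, and adjusted p = 0.00795 with an estimated correlation). NCL and NOP56 fell by 0.69 and 0.86. Another 4 lists were called at the preset correlation alone. Heat shock genes had 7 of 16 lower (8 lower and 1 higher adjusted over the list alone, adjusted p = 1.44e-04, and adjusted p = 0.0506 with an estimated correlation), and p53 targets had 6 of 23 lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.00379, and adjusted p = 0.113 with an estimated correlation). Stress response genes had 10 of 26 lower and 1 higher (10 and 1 adjusted over the list alone, adjusted p = 0.00736, and adjusted p = 0.113 with an estimated correlation), and adrenergic regulators had 13 of 27 higher and 7 lower (13 and 8 adjusted over the list alone, adjusted p = 0.0203, and adjusted p = 0.233 with an estimated correlation). HSPA8 fell by 1.26, the mitochondrial serine enzyme SHMT2 by 1.69, and SIX3 and MEIS1 rose by 2.06 and 1.44. With BRM014, at lower totals, 13707 and 13768 genes were detected against 15279 and 15191. A total of 2498 genes were called, 1270 higher and 1228 lower, and 1622 without DMSO replicate 2 or 1648 without BRM014 replicate 1.

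**Figure D2:**
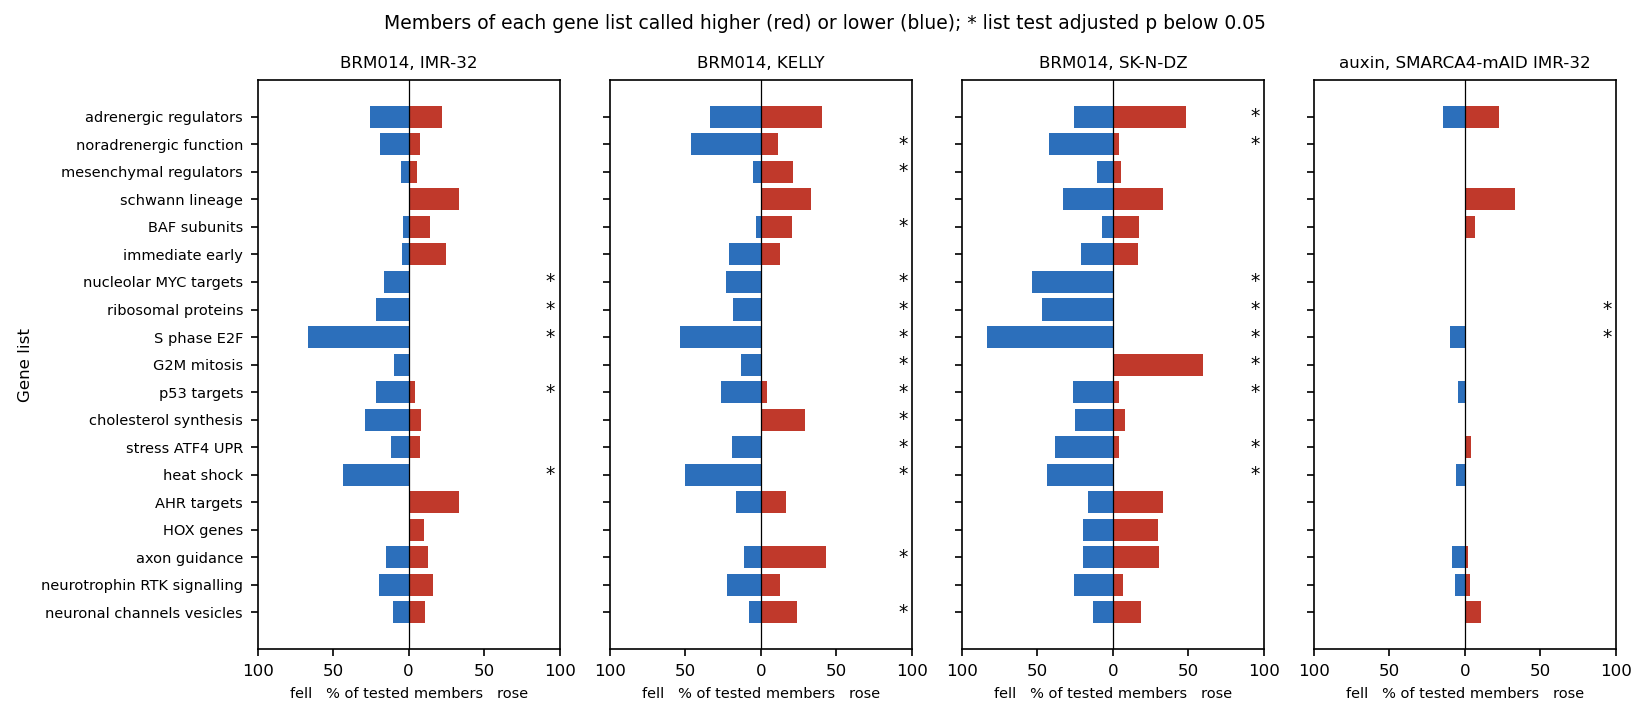
Percentage of tested members of each of 19 gene lists called higher (red, right) or lower (blue, left) in the 4 treatment comparisons, with asterisks where the list test had an adjusted p below 0.05 at the preset correlation. Lower DNA replication and E2F targets numbered 20, 16, 25 and 3 of 30, the auxin list call being lost at adjusted p = 0.318 with an estimated correlation, and G2/M genes rose in SK-N-DZ, in 18 of 30.

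**Figure D3:**
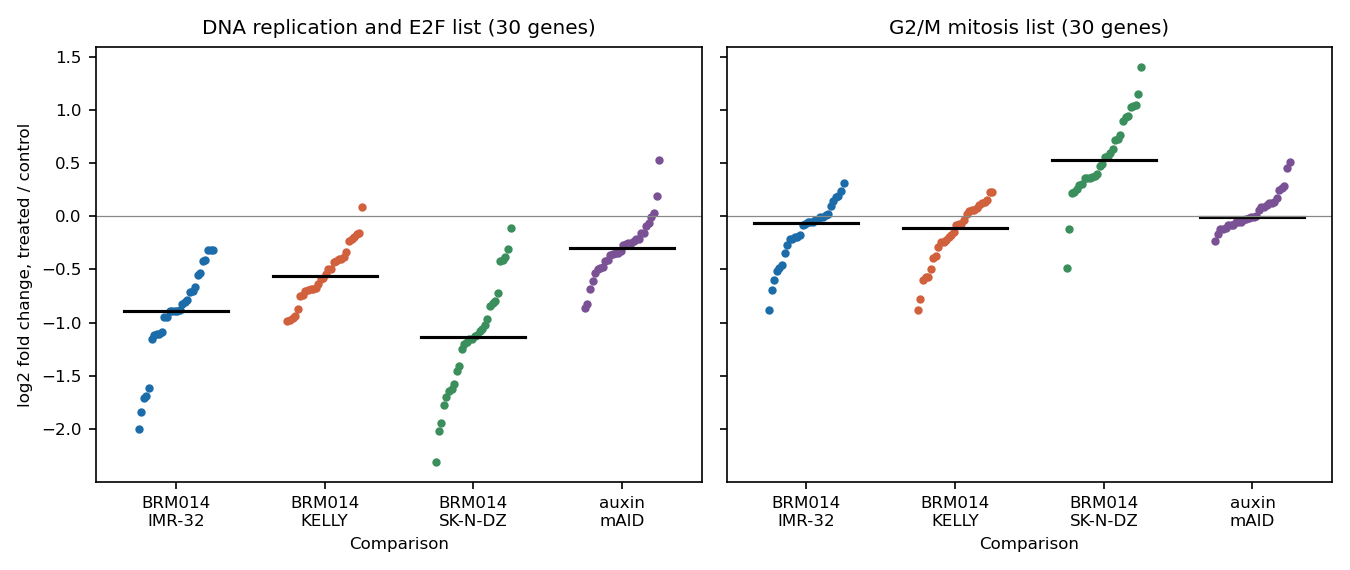
Log2 fold change of each of 30 DNA replication and E2F genes (left) and 30 G2/M genes (right) in the 4 comparisons, with points for genes in rising order and bars for medians. The medians of the replication list were -0.89, -0.56, -1.14 and -0.30, and the G2/M median in SK-N-DZ was 0.53.

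The transcription factors that define adrenergic neuroblastoma cells moved in different directions. MYCN (chromosome 2, 15940564 to 15947007) fell by 0.45 in IMR-32 (adjusted p = 2.94e-08) and by 0.52 in KELLY (adjusted p = 1.14e-10). It rose by 0.44 in SK-N-DZ (adjusted p = 2.69e-08), while the auxin change of 0.15 was not called (adjusted p = 0.255). TBX2 fell by 1.20, 1.80 and 1.69 in IMR-32, KELLY and SK-N-DZ. ISL1 fell by 0.42 in IMR-32 and rose by 1.79 in KELLY and 0.51 in SK-N-DZ; its IMR-32 call was lost without DMSO replicate 1 (-0.35). PHOX2A fell by 0.89 in KELLY and 0.76 in SK-N-DZ. GATA3 rose by 0.58 in SK-N-DZ, and HAND2 was not called in any of the 4 comparisons. With a correction for transcript composition and length that was added after the data were seen, MYCN in IMR-32 (-0.06, SE 0.06) and PHOX2A in KELLY (-0.31) and SK-N-DZ (-0.08) were no longer called. MYCN was then at -0.18 in KELLY and 0.98 in SK-N-DZ, TBX2 at -1.11 and GATA3 at 0.99 in SK-N-DZ. Calls gained were those of HAND2 in the 4 comparisons (0.43, 0.45, 0.81 and 0.44), GATA3 in IMR-32 (0.35) and KELLY (0.28), PHOX2A in IMR-32 (0.60) and MYCN in the auxin arm (0.29).

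**Figure D4:**
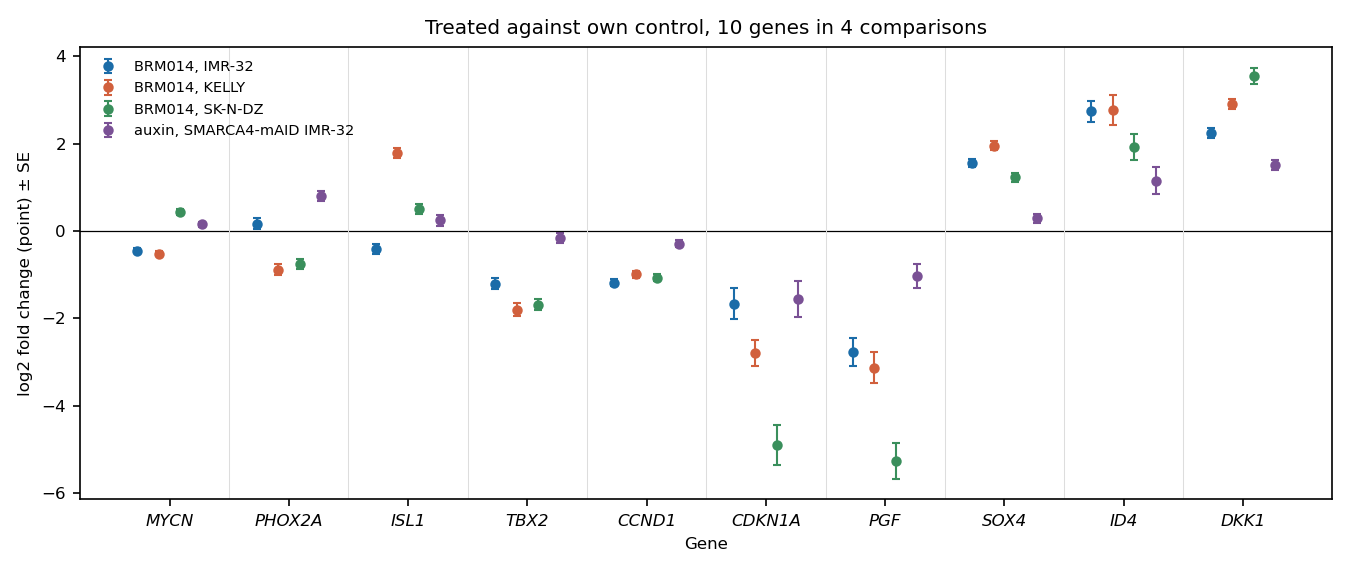
Log2 fold change (points) with SE (error bars) of 10 genes in the 4 treatment comparisons, each from 2 treated and 2 control libraries. DKK1 rose in all 4, by 2.24, 2.90, 3.56 and 1.51, while MYCN fell in IMR-32 and KELLY and rose in SK-N-DZ.

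Across the 3 lines, DKK1, ID4 and FAT4 rose and IGFBP4, PGF and CDKN1A fell with BRM014. The mean log2 change over lines was 2.90 for DKK1 (SE 0.08, adjusted p = 5.03e-51), 2.48 for ID4 (SE 0.17) and 2.42 for FAT4 (SE 0.21). It was -4.18 for IGFBP4 (SE 0.28), -3.72 for PGF (SE 0.21) and -3.12 for CDKN1A (SE 0.22), the last at -4.996 without SK-N-DZ BRM014 replicate 2. In the mean, 28 of 30 DNA replication genes fell and 0 rose (30 fell adjusted over the list alone, adjusted p = 3.98e-24, and adjusted p = 0.00653 with an estimated correlation). The same direction was called for 36 of 60 ribosomal protein genes (44 adjusted over the list alone, adjusted p = 6.49e-11, and adjusted p = 0.0150 with an estimated correlation), and for 21 after the correction for transcript composition and length. Lower calls were also made for 11 of 16 heat shock genes (11 adjusted over the list alone, adjusted p = 2.79e-07, and adjusted p = 0.0250 with an estimated correlation) and 15 of 30 nucleolar MYC targets with 1 higher (15 and 1 adjusted over the list alone, adjusted p = 1.62e-05, and adjusted p = 0.0306 with an estimated correlation). Lists of p53 targets (9 of 23 lower, 1 higher; 12 and 1 adjusted over the list alone, adjusted p = 9.68e-04), stress genes (11 of 26 lower, 2 higher; 14 and 2 adjusted over the list alone, adjusted p = 0.00407) and noradrenergic function (9 of 26 lower, 2 higher; 9 and 2 adjusted over the list alone, adjusted p = 0.0352) were called at the preset correlation. These had adjusted p = 0.0916, adjusted p = 0.105 and adjusted p = 0.0913 with an estimated correlation.

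The mean effect was called for 3879 genes, 1908 higher and 1971 lower. Higher calls in all 3 lines numbered 237 and lower calls 182, against 5.23 and 4.02 for independent lists. IMR-32 and KELLY shared 313 higher and 229 lower calls (52.9 and 42.1 for independent lists) with 40 in opposite directions. IMR-32 and SK-N-DZ shared 418 and 421 (79.5 and 80.7) with 49 opposite, and KELLY and SK-N-DZ 450 and 344 (83.5 and 61.1) with 31 opposite. Independent lists take every gene as equally likely to be called, which can set the expected numbers too low. Of the calls shared the same way, 488 of 542, 743 of 839 and 681 of 794 lay above the median level in these pairs. Across genes, which are not independent replicates, log2 changes correlated with Pearson r of 0.244, 0.289 and 0.338 and Spearman rho of 0.324, 0.394 and 0.398 in these pairs, and with r of 0.452, 0.541 and 0.545 among genes above the median level. Among such genes the changes followed GC content in each line (rho of -0.378 in IMR-32, -0.336 in KELLY and -0.486 in SK-N-DZ). A trend common to the lines can add to shared calls and correlations, which were not recomputed after the transcript property correction.

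The size of the BRM014 effect differed among lines for 831 genes, of which 92 were called in opposite directions in a pair of lines. RUNX1T1, a transcriptional co-repressor, fell by 1.13 in IMR-32 and rose by 1.36 in KELLY and 1.39 in SK-N-DZ. The semaphorin receptor NRP2 fell by 1.28 in IMR-32 and rose by 2.52 and 1.24. TIMP3 fell by 1.12 in IMR-32 and rose by 3.55 in KELLY, and RND3 rose by 2.43 in KELLY and 0.91 in SK-N-DZ, with 0.32 in IMR-32 (adjusted p = 0.103). EML5 fell by 1.56 in IMR-32 and rose by 0.79 in KELLY.

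Auxin, which triggers degradation of the tagged SMARCA4, called fewer genes. RGS16, a regulator of G-protein signalling, rose by 2.34 (SE 0.30, adjusted p = 2.48e-08), PDCD4 by 1.97 (SE 0.23), DKK1 by 1.51 (SE 0.12, adjusted p = 1.56e-17) and ARHGAP29 by 1.43 (SE 0.19). DCLK3 fell by 2.32 (SE 0.41), NRP1 by 2.14 (SE 0.21, adjusted p = 9.16e-13) and the co-repressor RCOR2 by 2.06 (SE 0.27). PHOX2A rose by 0.80, HAND1 by 1.37 and SIX3 by 1.03. The adrenergic list of 27 had 6 members higher and 4 lower (10 and 7 adjusted over the list alone, adjusted p = 0.476), with a median of 0.10 and a mean of -0.05. The DNA replication list was called lower, with 3 of 30 members below and 0 above (5 and 0 adjusted over the list alone, adjusted p = 7.00e-07, and adjusted p = 0.318 with an estimated correlation). Ribosomal proteins were also called lower as a list with 0 of 60 members called (0 adjusted over the list alone, adjusted p = 0.00394, and adjusted p = 0.345 with an estimated correlation). UHRF1 fell by 0.83, a call lost without ethanol replicate 1 (-0.71), and HSPA8 fell by 0.39, a call lost without auxin replicate 1 (-0.37). In all 281 genes were called, 132 higher and 149 lower. The number was 131 without ethanol replicate 1, 148 without ethanol replicate 2, 158 without auxin replicate 1 and 135 without auxin replicate 2.

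The inhibitor and the degron moved many of the same genes in IMR-32 cells. Both called 88 genes higher and 83 lower, against 8.27 and 9.80 for independent lists, and 6 genes in opposite directions. Of the 171 calls shared the same way, 156 lay above the median level, which the numbers for independent lists do not allow for. Of the 1650 genes called with BRM014, 83.9% had the same sign with auxin. Across genes, r was 0.195 and rho 0.286, with r of 0.479 among genes above the median level. Among such genes the changes of both arms followed GC content (Spearman's rho of -0.378 with BRM014 and -0.263 with auxin). A trend common to both arms can add to shared calls, shared signs and r. These were not recomputed after the transcript property correction. The effects themselves differed for 250 genes, 136 (54.4%) with the BRM014 change above the auxin change, a share that was 44.2% of 258 genes when total counts were the only scaling. RGS4 fell by 1.12 with BRM014 and rose by 2.07 with auxin. SOX4 rose by 1.56 with BRM014 (0.29 with auxin, adjusted p = 0.122), CCND1, which encodes cyclin D1, fell by 1.18 and 0.29, and KIF21A rose by 0.96 (-0.12 with auxin, adjusted p = 0.730). The number was 140 without IMR-32 DMSO replicate 1, 150 without IMR-32 BRM014 replicate 1 or ethanol replicate 1, and 156 without auxin replicate 2.

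Without 4sU, few genes had any count. No count was seen in either unlabelled library for 10485 of the 12853 genes tested (81.6%), and 65 genes had a background above 20% of their labelled level. At the low totals of the unlabelled libraries, the absence of counts for a gene can also reflect sampling. The 5 genes with the most unlabelled counts were EEF1A2, an elongation factor (199 and 108 counts, 65.9% of its labelled mean), ACTB (5.15%), IGF2 (10.9%), SLC35E2A (33.7%) and PRR11 (33.4%), an order by count and not by percentage. MYCN stood at 0.232% and PHOX2A at 3.89%. The edgeR fit of labelled against unlabelled KELLY libraries called 2526 of 8443 genes, 2350 higher (93.0%) and 176 lower, but with total counts as the only scaling 353 genes, of which 18.4% were higher. Leaving out either KELLY DMSO library left 116 genes past the filter and gave 25 calls, and leaving out unlabelled replicate 1 or replicate 2 gave 1257 of 10949 or 1004 of 10966. The mesenchymal list was called lower with 1 of 9 members below and 0 above (1 adjusted over the list alone, adjusted p = 0.00246, and adjusted p = 0.764 with an estimated correlation) although its median was 0.15.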

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

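The tests of differences between lines and between inhibitor and degron were fixed before the data were examined, whereas the tests of list differences between lines were chosen after the list results of each line were seen, as were the thinned and property-corrected comparisons of auxin with BRM014 and their ratio of sizes.

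The BRM014 effect differed among the 3 lines for 831 genes, by the test of the difference itself. The smallest adjusted p belonged to RUNX1T1 (1.865e-22), TIMP3 (1.865e-22), ISL1 (3.374e-20), EML5 (4.644e-19), NRP2 (4.940e-19) and RND3 (1.406e-17). The G2/M list differed between SK-N-DZ and IMR-32 (adjusted p = 1.036e-18, and adjusted p = 0.00166 with an estimated correlation) and between SK-N-DZ and KELLY (adjusted p = 3.103e-20, and adjusted p = 0.00155 with an estimated correlation), with medians of 0.53 in SK-N-DZ, -0.07 in IMR-32 and -0.11 in KELLY.

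The BRM014 and auxin effects differed for 250 genes in the IMR-32 background. The BRM014 change minus the auxin change was -3.19 for RGS4, 1.27 for SOX4, -0.89 for CCND1, 1.08 for KIF21A, 0.84 for FAM84A and 0.92 for MAB21L1.

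Auxin called 281 genes where BRM014 called 1650 in IMR-32, a ratio of 5.87. Library size argues the other way, since with every library thinned to the smallest total the ratio was 8.25. A response of the same kind at a smaller size may account for part of the gap. It was weighed on 794 genes that BRM014 called the same way in KELLY and SK-N-DZ, whose libraries neither IMR-32 arm uses. A set chosen by its BRM014 response can leave out genes that only auxin moves. A partly different response could therefore give such a ratio too. The median auxin change of the 794 genes was 0.356 of the BRM014 one (0.340 after the correction for transcript properties). The bootstrap 95% interval over genes was 0.309 to 0.391. Genes are not independent replicates, so this interval leaves out variation between libraries. In the direction of KELLY and SK-N-DZ, 76.6% of these genes moved with auxin and 90.8% with BRM014. Auxin calls went that way for 88 genes and the other way for 17, against 419 and 18 with BRM014. A smaller response of the same kind could itself make effects differ, so the count of 250 genes does not speak against it. Such a response leaves open why RGS4 moved in opposite directions. Inhibition of SMARCA2 by BRM014, incomplete degradation and unequal treatment times were not tested.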

How the results depend on the processing

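Thinning, the transcript property correction and robust empirical Bayes were chosen after the data were seen, and the other alternatives before. Across 508 combinations of a named gene and a comparison there were 8424 alternative values, of which 8095 kept direction and side of the threshold, 229 lost the call, 62 gained it and 33 changed sign without being called in either fit. The 5 that reversed all did so under the transcript property correction, with log2 changes of 0.43 for HAND2 in IMR-32, 0.079 for ID1 in SK-N-DZ, and 0.29 for SMARCA4, 0.25 for MYCN and 0.067 for PHOX2A in the mean over lines. These follow from the correction, which removes the trend with base composition and length. With 2 libraries per group at these depths, the simulated IMR-32 comparison recovered 17.9% of 1.5-fold changes and 92.4% of 4-fold ones. Its changed genes were above a minimum mean count, and the simulation did not vary depth.

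Requiring an absolute log2 change of at least 1, which by construction keeps a subset, left 797 genes in IMR-32, 735 in KELLY, 1273 in SK-N-DZ, 122 with auxin, 1122 in the mean, 540 for differences among lines and 146 for BRM014 minus auxin. Leaving out 1 library at a time, where the lone library is assumed to vary like the other groups, gave 922 to 1110 genes in IMR-32, 872 to 1160 in KELLY, 1622 to 1893 in SK-N-DZ, 131 to 158 with auxin, 3314 to 3740 in the mean, 666 to 804 for differences among lines, 140 to 201 for BRM014 minus auxin and 25 to 1257 for labelled against unlabelled KELLY, where the lowest came from 116 genes past the filter. Fewer libraries are the construction of that alternative. The transcript property correction called 1351 genes in IMR-32, 1187 in KELLY, 1733 in SK-N-DZ and 2956 in the mean, of which 1079, 983, 1347 and 2275 were also called without it, with 6 of the mean in the opposite direction. The other alternatives moved none of these counts by over 1.5 times except in the labelled-unlabelled comparison, where median-of-ratios scaling gave 4062, total counts 353, the stricter filter 1439 and the replicate block 313. The cause was not tested. DESeq2 shifted the median of all genes in that comparison by -5.40 on the log2 scale.

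Same-numbered libraries did not deviate together (correlations of -0.002, -0.040, 0.015 and -0.009 in IMR-32, KELLY, SK-N-DZ and the auxin arm), so replicate numbers were not taken to pair samples. With a replicate block the counts were 1653, 1450, 2442 and 299 in these comparisons, 3759 in the mean, 849 for differences among lines and 272 for BRM014 minus auxin.

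The number of lists called fell with an estimated correlation to 1 of 5 in IMR-32, 5 of 13 in KELLY, 5 of 9 in SK-N-DZ, 0 of 2 with auxin, 4 of 7 in the mean and 0 of 1 in the labelled-unlabelled comparison. With fry it was 8 in IMR-32, 14 in SK-N-DZ, 1 with auxin, 15 in the mean and 13 in the labelled-unlabelled comparison. Thinning gave 1 with auxin, and in the labelled-unlabelled comparison a replicate block gave 2 and total counts 3. Thinning kept 4 of the 5 lists called in IMR-32, 11 of 13 in KELLY and 6 of 7 in the mean. A replicate block kept 12 of 13 in KELLY and 6 of 7 in the mean. The transcript property correction kept 4 of 5 in IMR-32, 12 of 13 in KELLY and 6 of 7 in the mean. The cause was not tested. Correlations across genes rose among genes above the median level to 0.452 for IMR-32 with KELLY, 0.541 for IMR-32 with SK-N-DZ, 0.545 for KELLY with SK-N-DZ and 0.479 for BRM014 with auxin. They were 0.318, 0.355 and 0.216 in the last 3 pairs with DESeq2. The cause was not tested.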

Other observations

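The trends with gene properties and the list comparisons below were chosen after the data were seen, and the tests of the weighed explanations were written before their results.

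Lists that passed in no treatment comparison still held called genes. Of 10 HOX genes tested 3 rose and 2 fell in SK-N-DZ (4 and 2 adjusted over the list alone, adjusted p = 0.137), with HOXD9 and HOXD8 higher by 2.14 and 1.52 and HOXC4 lower, at -1.85. Neurotrophin and receptor tyrosine kinase genes were lower in 8 of 31 cases and higher in 2 in SK-N-DZ (10 and 7 adjusted over the list alone, adjusted p = 0.137), and in IMR-32 5 rose and 6 fell (5 and 8 adjusted over the list alone, adjusted p = 0.739), where ETV5, a target of ERK signalling, rose by 1.41. Immediate early genes rose in 6 of 24 cases and fell in 1 in IMR-32 (7 and 4 adjusted over the list alone, adjusted p = 0.213), with a median of 0.09 and a mean of -0.12. EGR1 rose by 2.11. Of 3 Schwann lineage genes tested, ITGB8 rose in IMR-32, by 0.96 (1 adjusted over the list alone, list adjusted p = 0.213), a call lost under 5 alternatives, among them the omission of either DMSO library (1.01 and 0.89) or either BRM014 library (0.88 and 0.95). Aryl hydrocarbon receptor targets had 0 of 6 called with auxin, an indole (1 higher adjusted over the list alone, adjusted p = 0.273), and AHRR, its repressor, stood at a log2 ratio of 3.54 with 71 counts against 6 (adjusted p = 0.0579). The BAF list was not called outside KELLY, but BICRAL rose in all 4 comparisons, by 1.70, 1.65, 1.79 and 1.01, the last of which was not called without ethanol replicate 2 (0.65).

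Changes with BRM014 followed the length of the gene. Among 6399 genes above the median level, Spearman's rho across genes between gene span and the mean BRM014 change was 0.328, and 0.254 given base composition. The shortest 1280 genes (median span 8.63 kb) had 129 higher and 421 lower, with a median of -0.18, and the longest 1280 (median 170 kb) had 519 higher and 130 lower, with a median of 0.23.

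SMARCA4 was 8.23-fold higher in the ethanol-treated SMARCA4-mAID line than in DMSO-treated IMR-32 (log2 3.04, SE 0.14, adjusted p = 3.01e-33), in different vehicles. Scaling argues little, since SMARCA4 stood at the 99.1 percentile of all tested genes or higher under both scalings, although 112 genes had a higher ratio. A gain of the surrounding region is opposed by the 52 tested genes within 1 Mb, whose median log2 ratio was -0.00648 with an upper quartile of 0.22. The design names an engineered SMARCA4 gene, and effects of the inserted sequence on the transcript or its counting may remain open, as they were not tested. The lines differed in 343 genes higher and 449 lower in the engineered one.

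The fall of the DNA replication, ribosomal protein and heat shock lists over the 3 lines was also weighed against library size and against trends with composition. Thinning every library to the smallest total left a largest adjusted p of 4.865e-07 among the 3 lists. Changes with BRM014 did follow composition, with Spearman's rho across genes of -0.485 with GC content in the mean, against -0.182 to 0.154 for differences between replicates. After correction for T content, GC content and length the list medians were -0.74 for DNA replication (-0.91 before), -0.26 for ribosomal proteins (-0.46 before) and -0.37 for heat shock (-0.49 before). Trends with these 3 properties, taken from the longest annotated transcript, may account for part of the fall, and the correction left the rest. Gene span, which the BRM014 changes also followed, was not in the correction, so a trend with span remains open. A biological response to BRM014 is a hypothesis that remains, with RNA stability and 4sU uptake untested.

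The mean BRM014 effect was also set against other splits of the 12 libraries within lines. Of 100 splits, the real one included, 1 gave as many genes as the real one. The real split called 3740 genes in that fit, against at most 1235 in the others. The other splits mix treated and control libraries in a group or reverse the direction of a line. Lower counts therefore follow from any difference between treated and control libraries, whatever its source. As the libraries of a group may share a culture, chance differences between cultures cannot be excluded.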
